A study of Drosophila melanogaster with 3 samples.

How the data were processed

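Transgenic Drosophila melanogaster embryos that express a prd-eGFP fusion were profiled by chromatin immunoprecipitation with an antibody against GFP, in 3 biological replicates per the labels, each from its own biological sample. The unit of analysis was the peak list. Per the labels the assembly is dm6 and chromatin was sonicated. The peak caller, its version, the aligner and the read filters are not given in the sources used here. Each replicate has its own ranked and thresholded list, made from that library per the deposited index files, and 4 ranked and 4 thresholded lists belong to the series as a whole. One of the latter is named conservative and was the main list. The labels name a possible control experiment, which was not used here.

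The deposited lists give each peak a scaled score up to 1000, which falls as the irreproducible discovery rate (IDR) rises. The ranked lists of the authors also give the −log10 of the global IDR. Every peak of the thresholded lists had a score of 830 or more and a global IDR of 0.01 or less, tested on the files. The ranked list behind the conservative list held 145 further peaks that pass this threshold and are not in it; the reason is not given in the sources used here. The signal value of each peak is the deposited value of the authors' peak caller, on a scale not stated, and was used only to rank or filter peaks within a list. The summit is the deposited offset from the start of a peak. Because ranks by signal depend on the length of the list and on depth, no signal value was compared between lists. Read counts were not given, so depth is unknown, and the number of peaks per replicate may differ for that reason alone.

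The lists held 6846 peaks (conservative), 4029, 6740 and 5020 peaks (replicates 1, 2 and 3). Peaks on the 7 assembled chromosomes were analysed, which left 6831, 4025, 6699 and 5018. Sequence came from the dm6 reference genome and genes from Ensembl release 115 on the same assembly, restricted to protein-coding genes (13968 genes with 19275 TSS positions). No peak reached past the end of its chromosome. Coordinates are 1-based. Scripts were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

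Overlap of at least 1 bp between the replicates' own lists was compared with 1000 circular shifts of the longer list along its chromosomes (one-sided permutation test). The share of summits within 500 bp of a TSS was compared with 1000 random placements on bases other than N, keeping the number per chromosome (two-sided permutation test). A gene was bound if a summit lay in its body or within 2 kb. The share bound in each of 20 gene lists was compared with 10000 random lists of genes matched on the decile of gene length plus flanking intergenic length (two-sided permutation test, Benjamini-Hochberg over the lists). The lists were other pair-rule genes, segment polarity genes, genes downstream of prd (which overlaps the former pair), gap, head gap, Hox, Pax and paired-class, Toll receptor, dorsoventral, neural, mesoderm, muscle structural, Notch, Wnt and Hedgehog, EGFR and JAK/STAT, accessory gland, chorion and yolk, chemoreceptor, ribosomal protein and proteasome genes. Matches of 20 motifs and of 2080 6-mers within 100 bp of the summit were compared with the same peak's 2 windows centred 1 kb away. The test permutes the labels of the 3 windows within each peak, which gives an exact two-sided p, adjusted by Benjamini-Hochberg within each family. Peaks are not replicates: these p-values describe the peaks of these libraries, and the values of the 3 replicates' own lists give the spread. Calls were made at an adjusted p of 0.05.

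The tests, lists, motifs and main alternatives were fixed before the data were examined. So was the rule for genes named in the text, which takes prd, every pair-rule, segment polarity and Toll receptor gene with its strongest peak, the gene with the TSS nearest to each of the 25 strongest peaks, and 2 to 4 members of other lists with the strongest peaks. A result on a single gene that this rule names is not reported here. Alternatives covered the other series-level lists, each replicate's own list, peaks found in all 3 lists, leaving out each replicate, a global IDR of 0.01 or less, the 1000 strongest peaks, other distances and windows, GC-matched random windows outside the peaks, nearest-TSS assignment and no matching on length. A global IDR of 0.001 or less was added, chosen after seeing the data, because a limit of 0.01 removes no peak. Alternatives of the overlap used 100 shifts.

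Each test was tested on simulated data, in part only after the first look at the deposited files. For the overlap, 51.4% of 4000 simulated peaks were found shared where 50% had been planted and chance adds some. For the share near a TSS, 29.3% was found and 29.3% expected over 2000 summits, as a mean of 10 sets that replaced a single set whose share had come out low, and 2.5% of random sets had a p under 0.05. For gene lists, 3.1% of 1000 random lists had an unadjusted p under 0.05, and lists with 80% of members bound were called in 10% of trials with 10 members, 40% with 15 and 100% with 85, so short lists are rarely called. For motifs, 3 of 3 planted sites and 0 of 17 others were called over 6831 windows, with a found excess of 2.05, 2.09 and 3.70 percentage points where 2, 2 and 5 had been planted. For 6-mers, 5 of 5 planted words and 0 others were called over as many windows. There is 1 group, so no comparison between groups, paired analysis or count of other splits applies, and outliers are not tested with 3 samples.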

Results

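Chromatin immunoprecipitation followed by sequencing was used to map where a green fluorescent protein fusion of Paired lay in the genome of Drosophila melanogaster embryos. Paired (Prd) is a pair-rule transcription factor with a paired domain and a homeodomain, and it activates segmentation genes such as en, wg and gsb. Whole embryos were collected 0 to 8 h after egg laying, chromatin was sonicated to fragments of 200 to 800 bp, and an antibody against the fluorescent protein was used for the precipitation. The series holds 1 group of 3 biological replicates. No control or input sample was analysed here, so every comparison is made within this group or against the genome sequence and its annotation. The files are peak lists without read counts. The depth of each library is therefore unknown, and no interval that needs it is given.

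The replicates shared most peaks of the shorter of their lists, while the longest list held many of its own. The own lists of replicates 1, 2 and 3 held 4025, 6699 and 5018 peaks on the assembled chromosomes, a mean of 5247 ± 1352 (SD, n = 3). Of the peaks of replicates 1, 2 and 3, 3006 (74.7%), 3004 (44.8%) and 3037 (60.5%) were overlapped in both other lists, and 336 (8.35%), 2073 (30.9%) and 644 (12.8%) in neither. Peaks found in all 3 lists had the higher signal values, with a median rank at 38.8% of the list in replicate 1 against 84.2% for the peaks that it alone held. Because the lists differ up to 1.66-fold in length, overlap was expressed as a share of the shorter list.

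Replicates 1 and 2 shared 3509 peaks (87.2% of the shorter list), replicates 1 and 3 shared 3186 (79.2%), and replicates 2 and 3 shared 4183 (83.4%). The mean over the pairs was 83.2% ± 4.01 (SD, 3 pairs that share replicates). Circular shifts of one list along its chromosomes gave 2.91%, 2.16% and 2.91% on average, so the observed overlap was 29.97-fold, 36.7-fold and 28.7-fold higher. Each pair had a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. Of the 6831 peaks of the conservative list on these chromosomes, 44.3% were overlapped in all 3 replicates. That share was 98.7% among its 1366 peaks with the highest signal values.

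**Figure D1:**
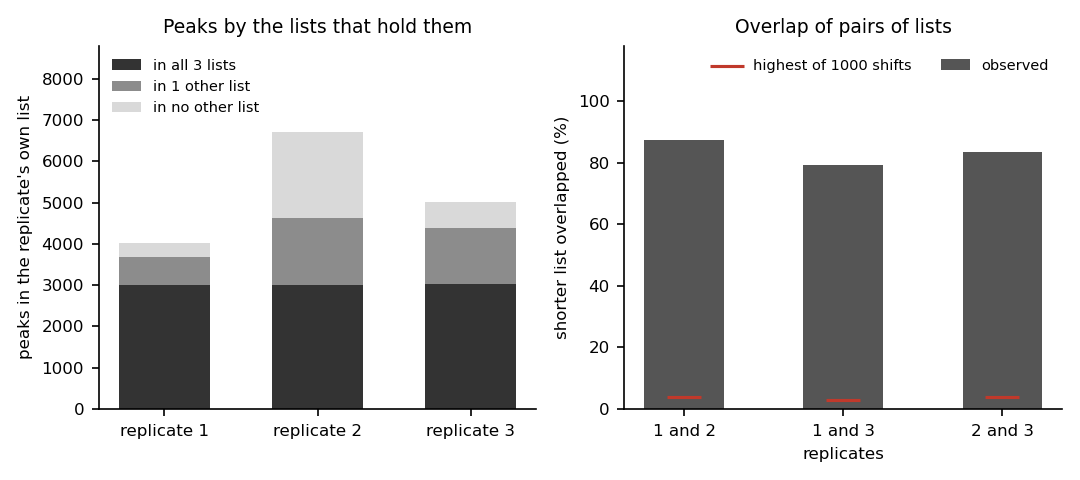
Left, peaks in each replicate's own list (y axis, number of peaks) by how many of the other replicates' lists overlap them. Right, percent of the shorter list overlapped by the longer one for each pair of replicates (bars), with the highest of 1000 circular shifts (red lines). About 3000 peaks of each list lie in all 3 lists, and the observed overlap of 79.2% to 87.2% stands far above the shifts.

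Promoters held a larger share of the peaks than their share of the genome. In the conservative list 2500 of 6831 summits (36.6%) lay within 500 bp of an annotated transcription start site (TSS), against 11.5% ± 0.393 (SD over 1000 random placements), which is 3.19-fold more. The share was 43.8%, 35.5% and 38.2% in the own lists of replicates 1, 2 and 3, a mean of 39.1% ± 4.21 (SD, n = 3). The two-sided permutation p was 0.002 for each of these 4 lists, the smallest that 1000 placements can give. Summits near a TSS lay mainly just upstream of it: 82.2% were upstream, at a median position of -105 bp with quartiles of -186 and -36 bp.

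Coding exons were nearly free of summits, with 45 summits (0.659%) against 14.1% of random positions. The 3′ UTRs held 0.878% against 4.55%. Introns held 37.3% of summits and 39.3% of random positions, and intergenic sequence held 24.1% and 29.9%. These shares are described without a test. The summits with the highest signal values were the closest to promoters: 47.7% of the strongest 1366 lay within 500 bp of a TSS, against 30.1% of the weakest 1367. More than 1 kb from any TSS lay 3736 summits (54.7%).

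**Figure D2:**
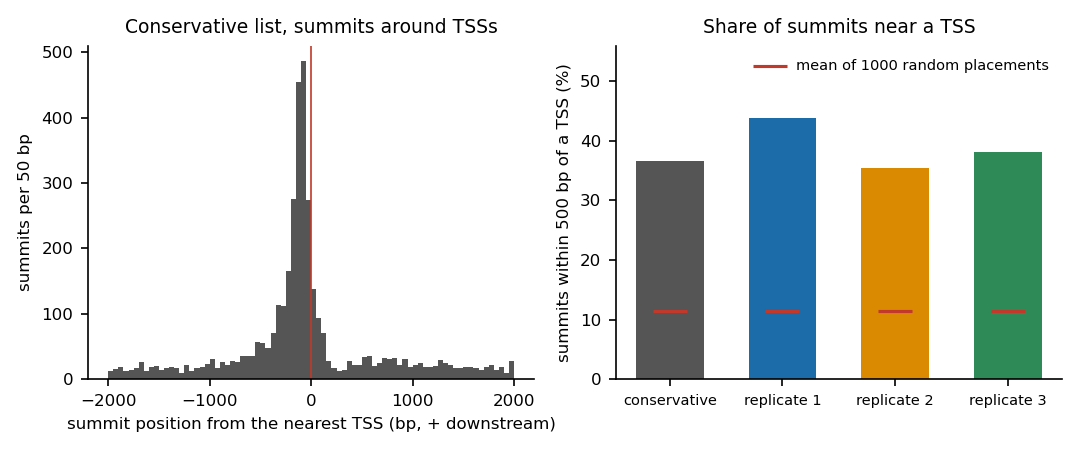
Left, number of conservative-list summits per 50 bp (y axis) by position from the nearest TSS in bp (x axis, positive values downstream). Right, percent of summits within 500 bp of a TSS in the conservative list and in each replicate's own list (bars), with the mean of 1000 random placements (red lines). The summits pile up just upstream of the TSS, at a median of -105 bp, and each list exceeds the random share of about 11.5%.

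Which genes lay beside the peaks was asked with 20 gene lists, counting a gene as bound when a summit fell in its body or within 2 kb of it. By that rule 5669 of 13968 protein-coding genes (40.6%) were bound. Of the 9 genes that genetics places downstream of prd, 8 (88.9%) had a summit, against 45.1% of genes matched on length. Those 9 genes are all members of the pair-rule or segment polarity lists, so these lists share hits and are not independent. A summit was found at 7 of 8 pair-rule genes other than prd (87.5% against 45.8%) and at 7 of 10 segment polarity genes (70% against 45.7%). After adjustment over the lists these differences did not pass the test: the two-sided permutation p was 0.02 for the downstream list, 0.043 for the pair-rule list and 0.22 for the segment polarity list, and the adjusted permutation p was 0.13, 0.13 and 0.4. The share lay above that of matched genes in 3, 2 and 3 of the 3 replicates. Without replicate 2 or 3, that is in peaks shared by the remaining pair, the share of pair-rule genes fell below that of matched genes (25% against 29.4% and 30.9%). That of downstream genes was 44.4% against 28.9% without replicate 2 and 33.3% against 30.5% without replicate 3. The share of Hox genes, 87.5% against 46.6% in the conservative list, stayed above that of matched genes. It was 62.5% against 29.98% without replicate 2 and 50% against 31.4% without replicate 3. These Hox differences did not pass the adjusted test (adjusted permutation p of 0.13, 0.46 and 0.8).

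The replicates differed at these genes. The share of downstream genes with a summit was 44.4%, 88.9% and 100% in replicates 1, 2 and 3, against 33.3%, 45.4% and 38.9% of matched genes. That of pair-rule genes was 25%, 75% and 87.5%, against 33.8%, 46.6% and 39.5%. Of the Hox genes, which set segment identity, 62.5%, 75% and 100% had a summit, against 34.3%, 47.6% and 40.4% of matched genes. Their strongest peaks lay in introns of Antp (rank 421), Ubx (rank 1006) and Abd-B (rank 1495). In the own list of replicate 3, 7 lists had more bound members than matched genes: the downstream, pair-rule, segment polarity, Hox, dorsoventral, EGFR and JAK/STAT, and ribosomal protein lists. The adjusted permutation p of the downstream list was 0.004 there and ran from 0.0027 to 1 over all alternatives and lists of equal length. Those of the pair-rule and dorsoventral lists, 0.049 each, lie at the edge of the threshold. At equal length replicate 3 had 6 such lists, and the dorsoventral list lost its call (adjusted permutation p = 0.23). Replicate 2 then bound 44.4% of downstream and 37.5% of pair-rule genes. The number of such lists was 4 with the 8720-peak list of the series and with assignment to the nearest TSS, which both called the downstream list (adjusted permutation p of 0.03 and 0.015) and the pair-rule list (0.046 and 0.029, in a range of 0.029 to 1), and 1 in replicates 1 and 2. Differences between replicates were not tested for these lists.

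Among the pair-rule genes, slp1 and opa had their strongest peak in all 3 replicates. The peak of slp1, which encodes a forkhead transcription factor, spanned 3827755 to 3827987 on chromosome 2L, intergenic and 2241 bp downstream of its TSS, with a signal value of 447 (rank 1018 of the conservative list). That of opa lay in an intron at 4858074 to 4858348 on chromosome 3R, with a signal value of 523 (rank 795). The strongest peaks of eve (rank 4272, 1793 bp downstream of the TSS), hry (rank 4028, 5256 bp downstream) and slp2 (rank 2409, 4341 bp downstream) were found in replicates 2 and 3. The peak of odd (rank 5363) lay 143 bp downstream of the TSS and was found in replicate 3 only. The strongest peak of ftz (rank 5974) was in a 3′ UTR and in no replicate's own list. The remaining pair-rule gene, run, had no peak in the conservative list.

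Of the segment polarity genes, en, inv, wg, ptc and nkd had their strongest peak in all 3 replicates. That of en, a homeobox gene, lay in the promoter at 11527924 to 11528061 on chromosome 2R, 120 bp upstream of a TSS (signal value 274, rank 2049). That of wg, which encodes a Wnt ligand, lay in an intron at 7313564 to 7313761 on chromosome 2L (signal value 293, rank 1908). The Hedgehog receptor gene ptc had 5 peaks, the strongest in an intron (rank 2164), and nkd had 4, the strongest in the promoter (rank 730). The intronic peak of inv ranked 3310. Peaks of hh (rank 3562, replicates 1 and 3) and gsb (rank 3939, replicates 2 and 3) were found in part of the replicates. The genes gsb-n, ci and mid had no peak in the conservative list; ci lies on chromosome 4, where the ranked list behind it held 17 peaks against 1060 expected from length. The genes ey, toy and sv of the Pax list and bt of the muscle list, named after their values were seen, lie there too and count as not bound. Of the Toll receptor genes striped in the germ band, Tollo (rank 1479) and Toll-7 (rank 1706) were found in all 3 replicates, Toll-6 (rank 5488) in no replicate's own list, and 18w had no peak. The gene prd itself had 2 peaks, the stronger at 12082631 to 12083006 on chromosome 2L, 2559 bp downstream of its TSS, with a signal value of 128 (rank 4748). It overlapped a peak of replicate 3 only.

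**Figure D3:**
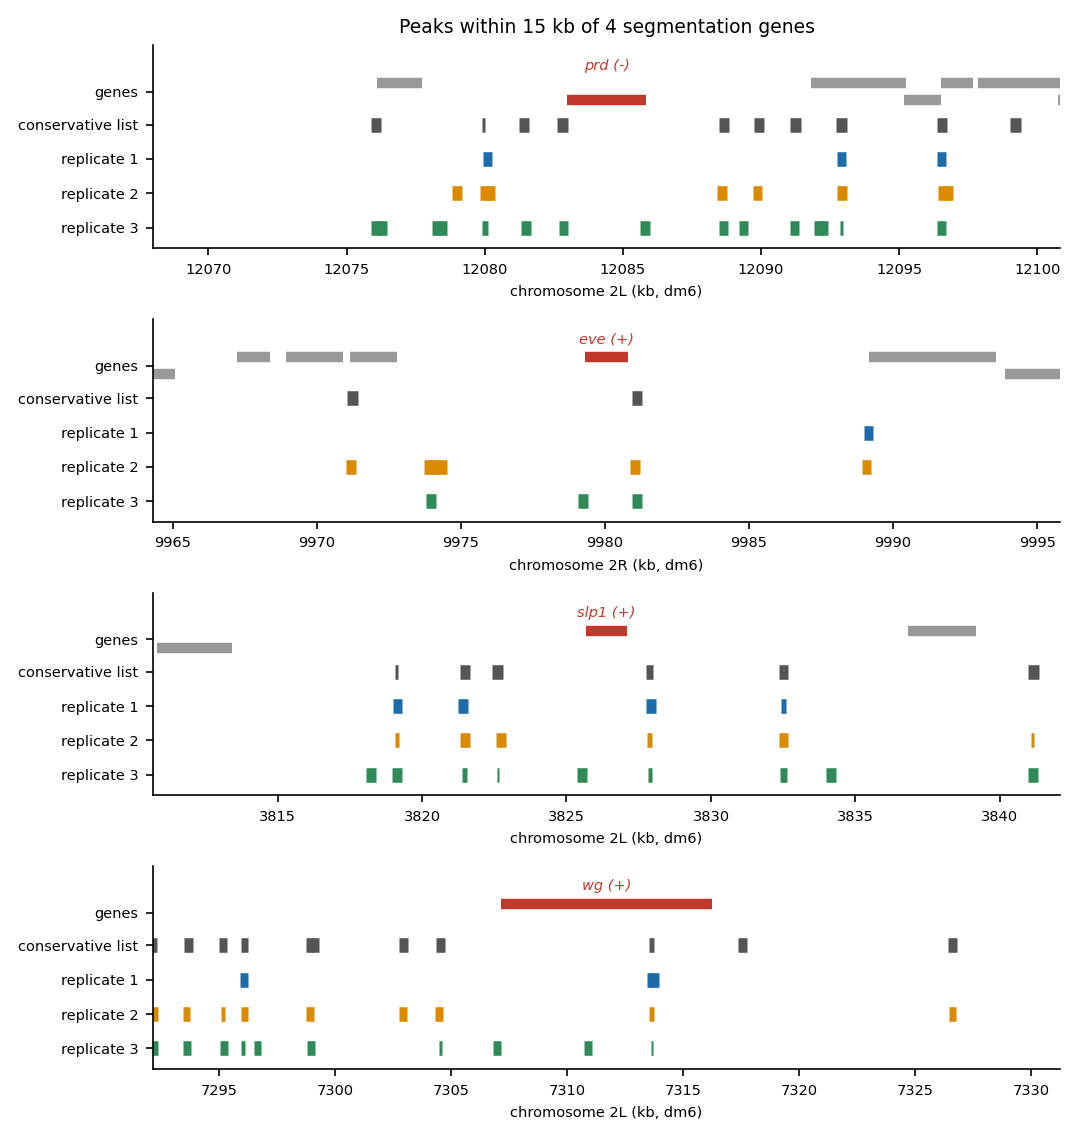
Peaks (bars) of the conservative list and of each replicate's own list within 15 kb of prd, eve, slp1 and wg, with the protein-coding genes above (red, the named gene), by position in kb on dm6. Replicate 3 has 15 peaks around prd, against 3 in replicate 1 and 8 in replicate 2, with overlapping peaks counted apart.

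In the conservative list, ribosomal protein genes were the only list whose share bound passed the adjusted test above that of matched genes. Of 85 such genes 60 (70.6%) had a summit, against 39.2% of matched genes, and 58.8%, 65.9% and 68.2% in replicates 1, 2 and 3 (mean 64.3% ± 4.90, SD, n = 3). Strong peaks beside them included those of RpL3 (rank 128), RpL34b (rank 247) and RpL32 (rank 253). That of RpL3 lay closest to the TSS of CG17726. The list of 111 chemoreceptor genes, which are used by adult sensory neurons, was the only one to pass it below: 8 genes (7.21%) had a summit, against 40.9% of matched genes and 6.31% ± 0.901 (SD, n = 3) bound in the replicates. The strongest peak beside them, near Or85f (rank 247), lay closest to the TSS of RpL34b, and the next was near Gr89a (rank 1074). The permutation p was 0.0002 for both lists, the smallest that 10000 random lists can give (0.002 adjusted), and the direction was the same in 3 of 3 replicates. The ribosomal call was lost when only summits inside the gene body were counted (8.24% bound, against 9.22% of matched genes) and with the 1000 strongest peaks (12.9% bound).

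In the conservative list no other list passed the test; counting these lists, 7 of the 20 had an unadjusted permutation p under 0.05. Bound were 11 of 15 Wnt and Hedgehog genes, 7 of 8 Hox genes, 10 of 15 Notch pathway genes, 10 of 15 EGFR and JAK/STAT genes, 10 of 16 dorsoventral genes, 8 of 14 Pax and paired-class genes, 8 of 13 mesoderm regulators and 3 of 4 Toll receptor genes. At or below the share of matched genes were 3 of 10 gap genes, 2 of 5 head gap genes, 5 of 14 neural genes, 3 of 12 muscle structural genes, 3 of 13 accessory gland genes and 1 of 12 chorion and yolk genes. Proteasome genes had 19 of 48 members bound (39.6%), against 39.0% of matched genes, with the strongest peaks near Rpn5 (rank 114) and Prosalpha4 (rank 476).

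**Figure D4:**
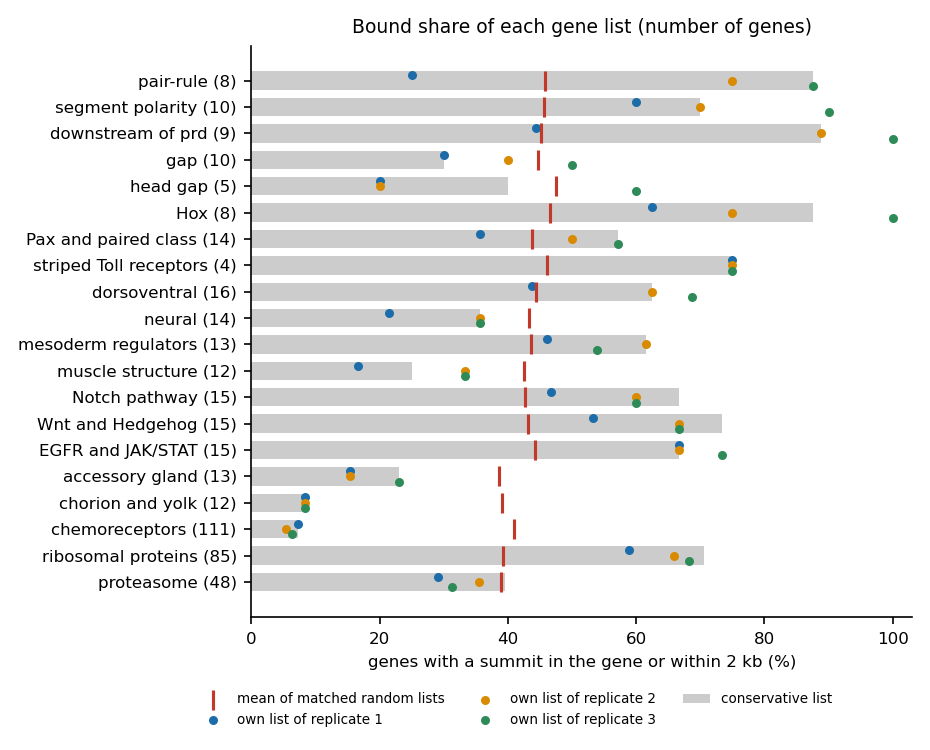
Percent of the genes of each list with a summit in the gene or within 2 kb (x axis) in the conservative list (grey bars) and in each replicate's own list (points), with the mean of length-matched random lists (red lines). Ribosomal proteins lie above the red line and chemoreceptors below it in each replicate, while the points of the pair-rule list spread from 25% to 87.5%.

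The strongest peaks lay mainly at promoters and beside none of the segmentation genes listed. The 25 peaks with the highest signal values (2606 to 5399) were all found in all 3 replicates, 19 of them lay within 500 bp of a TSS, and none of the genes with the nearest TSS was in any of the 20 lists. The strongest lay at 19590430 to 19590813 on chromosome 3L, 92 bp upstream of CG14100. The next lay upstream of a TSS of Ugalt, which encodes a nucleotide sugar transporter (40 bp), ph-p, a Polycomb group gene (494 bp), CG7601 (107 bp) and Tcs5 (108 bp). The summit at ph-p lay inside that gene. Promoter peaks among the 25 also belonged to px, Art3, Chro, CenG1A, CG5611, mRpL41, Sox14, CG13921, Shc, eIF6, mRpL23, PNPase, CG1888 and CG8320. Intronic peaks lay closest to Adf1 (799 bp), CG11050 (1033 bp), CG32772 (1255 bp) and HmgZ (559 bp), and intergenic ones to tara (3167 bp) and CG13323 (11912 bp).

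Whether known binding sites mark the summits was asked with 20 motifs fixed beforehand, by comparing the 100 bp on each side of a summit with windows of the same width centred 1 kb to each side. The core of the site of the paired domain, GTCACGS, was not enriched: it occurred at 1.80% of summits and in 1.71% of flanks (ratio 1.05, exact p = 0.690, adjusted exact p = 0.726). The palindromic homeodomain sites, which paired-class homeodomains bind as dimers, were enriched. TAATNNATTA, the P2 site, stood at 2.37% against 1.37% (ratio 1.73, replicates 1.92 ± 0.216, SD, n = 3, adjusted exact p = 1.38e-06). TAATNNNATTA, the P3 site, stood at 2.74% against 1.73% (ratio 1.58, replicates 1.64 ± 0.0976, adjusted exact p = 7.40e-06). The largest ratios belonged to sites of promoter factors. The site of DREF, a factor of promoters of growth and housekeeping genes, stood at 2.94% of summits against 0.512% (ratio 5.74, replicates 5.49 ± 0.887), and that of M1BP, another core promoter factor, at 1.38% against 0.300% (ratio 4.59, replicates 4.05 ± 0.333). The adjusted exact p was 8.50e-42 and 1.07e-16, and the direction of these 4 sites was the same in 3 of 3 replicates.

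In all, 7 motifs were more frequent at summits and 4 less frequent at an adjusted exact p under the threshold of 0.05. The other enriched motifs were the homeodomain monomer (ratio 1.17), the relaxed site of the pioneer factor Zelda (1.17) and the T-rich site of Hunchback (1.82). Less frequent were the sites of Ftz-F1 (0.417), Snail (0.7) and Runt (0.715) and the GAGA site (0.798). The GAGA ratio was 0.866 and 0.634 in replicates 1 and 2 and 1.09 in replicate 3. Sites of Twist (1.09), Caudal (1.06), Sox (0.929), Bicoid (0.921), Opa (0.917), Zelda in its strict form (0.859) and Grainyhead (0.7) passed the test in neither direction, and the composite of a homeodomain half-site and the paired-domain core was found at 1 summit.

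The comparison sequence mattered for several of these sites. Summits were poorer in G and C than their flanks (36.2% against 42.5%). The other windows used were matched in GC content but also lay at random places away from the peaks, so the source of a change was not separated. Against random windows of the same GC content outside the peaks, the paired-domain core was 1.54-fold enriched (adjusted exact p = 0.00130). The P2 site was 1.30-fold enriched (adjusted exact p = 0.0198), but 1.22-fold with another draw of windows (exact p = 0.0452, unadjusted), so its call may depend on the draw. The P3 site was 1.05-fold enriched (adjusted exact p = 0.614). The GAGA site turned to a ratio of 1.60 and the homeodomain monomer to 0.936. Over all alternatives the adjusted exact p ran from 0.00130 to 1 for the core, from 4.31e-13 to 0.123 for the P2 site and from 7.97e-10 to 0.614 for the P3 site. Distance from promoters mattered as well: among summits more than 1 kb from a TSS, 2 motifs were enriched, the relaxed Zelda site and the Hunchback site. The DREF ratio was 0.824 beyond 1 kb, against 14.2 within 500 bp of a TSS. The P2 and P3 ratios were 1.38 and 1.26 beyond 1 kb (adjusted exact p = 0.123 and 0.204), against 2.93 and 2.51 within 500 bp.

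**Figure D5:**
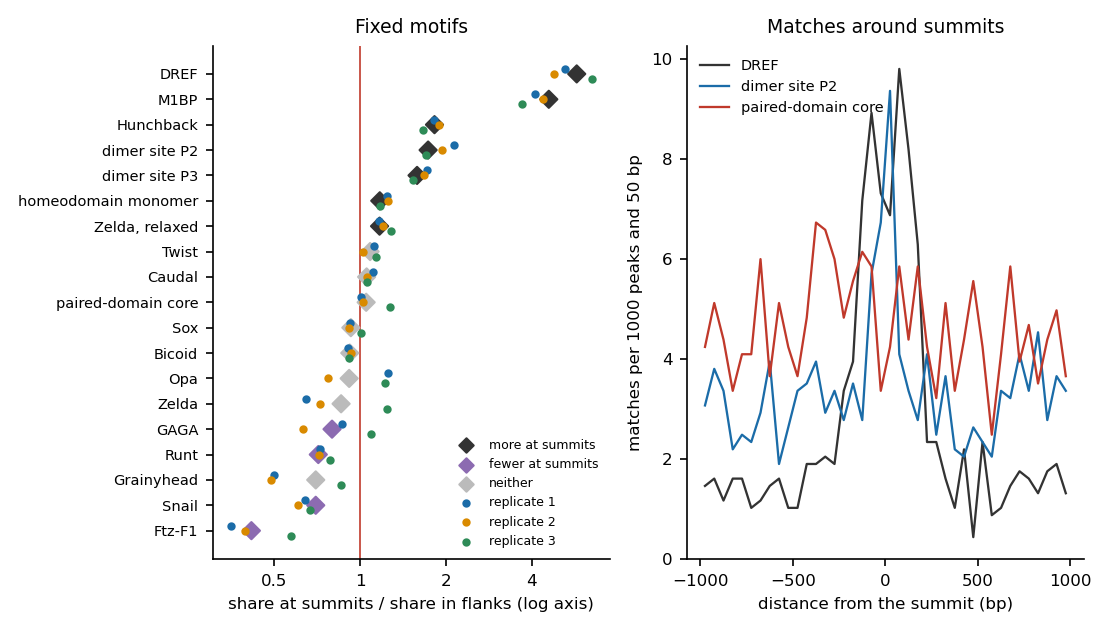
Left, ratio of the share of conservative-list summits with a match to the share of flank windows with one (x axis, log scale; diamonds), with each replicate's own list as points; the composite site is left out. Right, matches per 1000 peaks and 50 bp (y axis) by distance from the summit in bp. The DREF site has a ratio of 5.74 and the paired-domain core one of 1.05.

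A search over all 2080 6-mers, with reverse complements merged, gave 558 that were more frequent at summits and 1098 that were less frequent. Of the former, 461 were also more frequent in each of the 3 replicates' own lists. The 36 6-mers made of A and T alone were all more frequent. The highest ratio belonged to ACACTG, which stood at 19.3% of summits against 7.49% of flanks (ratio 2.58, 2.497 to 2.61 in 3 of 3 replicates, adjusted exact p = 1.32e-126). The next were AGTGTA with a ratio of 2.56, GTGCAC with 2.42 and ACAGTG with 2.40. Against windows of matched GC content 429 6-mers were more frequent, and 242 of them were among the 558.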

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

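The counts in this part were taken after the data were seen, and no test was run on them. Peaks on unplaced contigs entered no comparison of the report, and their numbers exceeded the limit of 3 that a count of 0 allows in 3 of the 4 lists examined: 15 in the conservative list, 4 in the own list of replicate 1 and 41 in that of replicate 2. The list of replicate 3 held 2. All of these peaks lay on contigs assigned to chromosome X without a position, 28 contigs in replicate 2 and 12 in the conservative list, and the best of them ranked 563 by signal value in the conservative list. Their genes and distances to a TSS were not analysed here. With 3 replicates in 1 group, neither outlying samples nor differences between groups could be looked for.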

How the results depend on the processing

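The global IDR limit of 0.001 and all alternatives of the spaced word and of the peaks of replicate 3 alone were chosen after seeing the data; the others were planned. Overlap stayed above the shifts at each alternative (66.0% with reciprocal overlap of 50%, 76.7% with lists of equal length, 88.1% at the IDR limit of 0.001; 79.2% to 87.2% without one replicate), at a permutation p of 0.0099, the smallest that 100 shifts can give. The share of summits near a TSS ran from 26.7% (200 bp) to 51.3% (1000 strongest peaks) and stayed above its background in each case (39.0% to 44.4% without one replicate). A limit of 0.01 removes no peak and tests nothing.

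The number of gene lists above matched genes, 1 in the main list, was 4 with the 8720-peak list and with nearest-TSS assignment, 7 in the own list of replicate 3, 2 within 5 kb, and 0 with gene bodies only and with the 1000 strongest peaks; without one replicate it was 1 to 1. Gained were the downstream list (8720-peak list, nearest TSS, replicate 3, within 5 kb), the pair-rule list (the first 3 of these), Wnt and Hedgehog genes (8720-peak list), EGFR and JAK/STAT genes (nearest TSS, replicate 3) and segment polarity, Hox and dorsoventral genes (replicate 3). For gene bodies and strongest peaks fewer genes are bound at all; otherwise the cause was not tested. Of the comparisons of single lists, 291 kept direction and side of the threshold, 14 passed it newly, 1 no longer did and 34 turned direction. Turned were ribosomal genes with gene bodies only (8.24%), which lost their call, and lists without a call on either side, whose cause was not tested. Pair-rule genes turned in replicate 1 and in peaks shared by all 3 replicates (25% each), in the 5856-peak list (37.5%), with the 1000 strongest peaks (12.5%) and without one replicate (25% to 75%; below matched genes without replicate 2 or 3). With the 1000 strongest peaks Hox (12.5%), segment polarity (10%), downstream (0%) and Toll receptor genes (0%) turned too. Toll receptor genes also turned with gene bodies only and with the IDR limit of 0.001 (25% each). Pax and paired-class genes turned in the 5856-peak list (35.7%) and without replicate 3 (28.6% to 42.9% without one replicate), and muscle structural genes without replicate 1 (16.7% to 33.3%). Gap (50%) and head gap genes (60%) turned in replicate 3, head gap genes also within 5 kb and by nearest TSS (100% each), and neural genes in the same pair of settings (64.3% each) and with gene bodies only (28.6%). Proteasome genes, next to their matched share, turned in replicates 1, 2 and 3 (29.2%, 35.4%, 31.25%), the 5856-peak list (33.3%), the 1000 strongest peaks (8.33%), the IDR limit of 0.001 (27.1%), gene bodies only (6.25%), within 5 kb (52.1%), without matching (39.6%) and without replicate 1 or 3 (27.1% to 27.1% without one replicate).

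The number of enriched motifs, 7, was 6 to 9 except among summits over 1 kb from a TSS, where it was 2, with fewer peaks and no promoters (7 to 8 without one replicate). Of the comparisons of single motifs, 284 kept direction and side (a ratio of 1.00 counted as kept), 21 passed the threshold newly, 23 no longer did and 32 turned direction, from causes not tested. With a call in at least one of the settings compared, these were GAGA 1.09 in replicate 3, 1.37 with 200 bp around the summit and 1.60 against GC-matched windows; homeodomain monomer 0.936, Snail 1.06 and Opa 1.69 against GC-matched windows; Bicoid 1.19 with 50 bp; and homeodomain monomer 0.998, DREF 0.824 and Caudal 0.915 beyond 1 kb. With no call in either, these were the paired-domain core (0.997 in the 8720-peak list, 0.778 with the 1000 strongest peaks, 0.855 with 50 bp, 0.860 beyond 1 kb), strict Zelda (1.25 in replicate 3, 1.31 against GC-matched windows, 1.23 beyond 1 kb), Caudal (0.947) and Grainyhead (1.47) against GC-matched windows, Grainyhead with 200 bp (1.28), Sox in replicate 3 (1.01), the composite site with flanks at 500 bp and GC-matched windows (2.00 each) and Opa (1.25 and 1.22 in replicates 1 and 3, 1.01 in the 5856-peak list, 1.48 in peaks shared by all 3, 1.56 with the 1000 strongest peaks, 1.37 with the IDR limit of 0.001, 1.01 to 1.47 without one replicate). Enriched 6-mers numbered 377 to 568 (502 to 541 without one replicate); against GC-matched windows 242 of 429 were shared with the main list. The spaced word and the core at peaks of replicate 3 alone kept direction and side in 16 and 6 comparisons. Unknown depth limits every comparison of list lengths.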

Other observations

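Tests on the spaced word, on peaks held by a single replicate, on dimer spacing, on the surroundings of prd and on chromosome 4 were chosen after the data were seen, following looks at signal ranks, longer words and masked sequence; nearest-TSS assignment was planned.

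The 644 peaks that replicate 3 alone held gave a summit to 8 of the 9 genes downstream of prd, against 0.838 expected (adjusted permutation p = 0.004). They gave one to 7 of 10 segment polarity genes and to 5 of 8 pair-rule genes other than prd. All downstream genes belong to the segment polarity or pair-rule list, so these hits overlap. The dorsoventral (6 of 16), Wnt and Hedgehog (5 of 15), Hox (4 of 8) and ribosomal protein lists (9 of 85) passed the test as well, at an adjusted permutation p of 0.007, 0.012, 0.037 and 0.0096, while gap genes (3 of 10) did not (0.18). The peaks carried the paired-domain core GTCACGS at 4.19% of summits against 1.48% of flanks (ratio 2.84, adjusted exact p = 0.00366), the Zelda site at 4.50% against 0.776% and the GAGA site at 7.45% against 2.95%. The DREF (ratio 5.60), Grainyhead (8.00) and relaxed Zelda sites (1.73) passed the exact test as well, and the homeodomain monomer, Bicoid, Caudal and Hunchback sites were less frequent than in flanks. These summits were richer in G and C than their flanks (45.3% against 41.5%). Against GC-matched windows the less frequent sites passed the exact test no longer (ratios of 0.964, 0.766, 1.09 and 1.22, the last pair turned in direction), nor did Grainyhead (5.33, adjusted exact p = 0.0504), while the core (2.25), strict Zelda (3.22), relaxed Zelda (2.32), GAGA (3.56) and DREF sites (9.33) did, as did M1BP (6 summits and no window). The core, the strict Zelda site and the GAGA site, compared further after their values were seen, differed from the other replicates as follows. None of these 3 sites was enriched at the 336 peaks of replicate 1 alone or the 2073 of replicate 2 alone. In replicate 1 alone they stood at only 5, 3 and 9 peaks, so little can be read from it. In replicate 2 alone the GAGA site was less frequent than in flanks (ratio 0.541, adjusted exact p = 0.00366). The share with the core differed from that in replicate 2 alone (Fisher's exact p = 0.000775) and in replicate 1 alone (Fisher's exact p = 0.0231), unadjusted in a family of 6. Base composition was not matched between these sets: summits held 35.8% G and C in replicate 2 alone and 40.5% in replicate 1 alone, against 45.3% here. Examples of the peaks of replicate 3 alone lay at -73 bp from the TSS of eve, -120 bp from that of gsb and -127 bp from that of slp1. Another lay 23 bp downstream of that of prd, at 12085636 to 12085971 on chromosome 2L. Replicate 3 had 15 peaks within 15 kb of the TSS of prd, and no protein-coding gene had more in that list. The conservative list had 10 there and replicate 2 had 8, numbers that 0.208% and 1.07% of genes reached in these lists. Replicate 1 had 3, which 18.7% of genes reached. Peaks that overlap each other were counted apart, such as those of replicate 3 that start at 12078081 and 12078293, with signal values of 39.1 and 6.13.

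What sets the peaks of replicate 3 alone apart was weighed against technical explanations. List length was weighed on whole lists, with a bound written after the values were seen. At equal length replicate 3 still bound 9 of the 9 downstream genes and replicates 1 and 2 bound 4 each. That argues against a longer list as the source of the lead over replicate 1. For replicate 2 the cut cannot decide: its full list was longer than that of replicate 3 and bound 8, so most of that gap came with the cut. Base composition alone is argued against because only 2.34% of words made by permuting the core reached its ratio, although the ratio against GC-matched windows, 2.25, has a wide bootstrap interval (1.31 to 3.85). Whether these places lie just under the threshold in the other replicates cannot be told apart from a real difference, since 38.8% of the peaks were overlapped by the top of their ranked lists, between the bounds set. A different mean age of the embryos or a better precipitation may lie behind the difference. Neither was tested, nor was any other biological explanation, and the labels give the same age range for each replicate.

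Over all conservative-list summits a spaced word had a higher ratio than any of the 20 fixed motifs, though not at promoters, where its ratio was 5.35 and that of the DREF site 14.2. CACTGNNNRAAA stood within 100 bp of 16.2% of conservative-list summits against 1.39% of flanks, an 11.7-fold difference that was 10.02 ± 0.305 in the replicates' own lists (SD, n = 3), and 1307 of its 9544 sites in the genome lay there, 13.3-fold more than the genome share of those windows. It was most frequent in intergenic (27.2%) and intronic (20.1%) peaks and stood in 5.56% of promoter peaks and at 0 of 45 CDS peaks. Its matches beside summits over 1 kb from a TSS numbered 98.2 and 105 per 1000 peaks at 50 to 100 bp on either side, against 43.4 and 34.8 within 50 bp. An 8-mer search on chromosomes 2L, 2R and X chose CACTGAGA among 737 words, and on 3L and 3R that word had a ratio of 14.3 (exact p = 6.93e-54). Words of the same composition had ratios of 1.68 (CACTGNNNRTTT) and 2.14 (CAGTGNNNRAAA).

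Base composition and promoter sequence are argued against as sources of this word, with ratios of 12.1 against GC-matched windows and 14.9 among summits over 1 kb from a TSS. The bounds that decided both were written after the values were seen. Identical copies of a single repeat are argued against as well: at 0% of 1251 words did the 20 bases beside the word also stand beside another. Diverged copies would not share these bases, so the test cannot decide on them. Repeated sequence in general stays open, since only 98 peaks hold no soft-masked base at the summit or in the flanks. Their ratio of 2.00 rests on 3 peaks with the word. The word stood at 3.06% of these 98 summits, against 16.2% of all conservative-list summits. This count cannot show whether the bases of the word itself are masked. Of the 6831 peaks all but these 98 hold a masked base somewhere in the windows. The word may mark a factor that shares these places with the fusion protein or is recovered with any precipitated chromatin. No control sample was analysed that could separate these, no biological explanation was tested, and the word was found and tested on the same peaks.

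Neighbouring genes could account for summits near ribosomal protein genes where genes lie densely. With each summit given only to the gene with the nearest TSS, 43.5% of them were still bound, 2.06 times the share of matched genes (adjusted permutation p = 0.002), which argues against neighbours as the whole source. The peak beside RpL3 was nonetheless nearest to another gene. No biological explanation was tested, since the design has a single group.

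Homeodomain dimer sites TAAT and ATTA were enriched at each spacing from 0 to 8 bp, with ratios from 1.45 to 2.66, and the ratios of the P2 spacing (1.73) and the P3 spacing (1.58) were not the highest; against GC-matched windows they ran from 1.00 to 1.60. Chromosome 4 held 17 peaks of the ranked list behind the conservative list, against 1060 expected from its length, and 5 of the thresholded list.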
